A study of Homo sapiens with 18 samples.

How the data were processed

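Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out in U937, an established human acute myeloid leukaemia line, per the labels. The series lists 18 samples. H3K9me3 and H3K27me3 were each profiled in cells with a control guide (sgControl), in cells knocked out for SUV39H1 (SKO) and in cells knocked out for SUV39H1 and SUV39H2 (DKO), with 2 libraries per genotype and mark. SETDB1 was profiled in 2 libraries of wild-type (WT) cells. The 4 input samples came without a file and were not analysed here. Groups and replicate numbers were taken from the sample titles. The labels do not state that replicates came from separate cultures, so the spread between these libraries may be technical. The permutation tests of covered length measure that spread. The rotation tests described below keep the libraries fixed and measure how calls lie along the genome. Their p-values do not measure the spread between replicates. Whether the knockout lines were clones or pools is not given in the sources used here.

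Cells were fixed with formaldehyde and sonicated, and Drosophila S2 chromatin was added in fixed amounts as a spike-in (ChIP-Rx), per the labels' protocols. Libraries were made with a Nextera XT kit, per the labels' protocols. Trim Galore 0.6.10, FastQC 0.12.1, deepTools 3.5.6, SICER and the builds hg38 and dm6 are named in the submitters' processing notes. The aligner, the filters on reads and the handling of reads with several matches are not given in the sources used here. Olfactory receptors, zinc finger genes, protocadherins, keratin associated proteins and cancer testis antigens have near-identical relatives, so values of single members of these families are uncertain.

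The deposited H3K9me3 and H3K27me3 files are domain lists, made per library with epic2, an implementation of SICER that joins neighbouring enriched windows into broad domains. Each domain carries a read count of its own library and a score, as deposited by the authors. The count is not normalised for depth or for the spike-in, and the lists hold no input count, p-value or spike-in factor. The score is the authors' own value and was used here only to rank domains within a list. The smallest domain spanned 800 bp, the domain edges lay on an 800 bp grid, and neighbouring domains were at least 4000 bp apart. The SETDB1 lists hold narrow peaks called per library, with a score and a −log10 p-value per peak as deposited by the authors. No deposited SETDB1 peak had a −log10 p below 5.00, and the peak caller is not given in the sources used here. Without a spike-in factor, the lists show where domains were called and cannot show a change of the mark's total amount. They also cannot check the knockouts themselves, since no expression or sequence of the targeted genes was measured in them.

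Everything that follows was computed from those lists on chromosomes 1 to 22 and X of hg38, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene positions came from a RefSeq table of GRCh38.p14 with 19974 protein-coding genes. It gives no strand, so a planned window around transcription start sites was not run, and SETDB1 peaks were assigned to a gene within its body or 2 kb on either side. Chromosome length was taken as the farthest called base or annotated gene end, 3029 Mb in all. Covered length is the sum of domain lengths of a library. For positions, 10 kb bins were marked where at least 50% of the bin lay in domains. A bin was lost when it was marked in both libraries of the reference genotype and in neither of the other, and gained in the opposite case. For genes, the percentage of the gene body inside domains was taken per library. A gene was called lost or gained when the libraries of the genotypes did not overlap and the nearest pair differed by at least 25 percentage points. Each of these counts was repeated in the 2 other ways of pairing the same 4 libraries. These put 1 library of each genotype on either side, so bins and genes called by genotype cannot be called there. The level they give is therefore held low. For H3K9me3 genes against sgControl it was at most 60 in SKO and 49 in DKO, below the 73 to 87 false calls among simulated unchanged genes.

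The comparisons were SKO and DKO against sgControl and DKO against SKO for each mark. Covered length was tested for a trend over the number of SUV39H genes targeted by an exact two-sided permutation test over all 90 assignments, whose smallest p is 0.0222. A pairwise exact test of 2 against 2 libraries cannot go below p = 0.333 and was not used. The 23 gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives except 3. Each list was tested by an exact two-sided rotation test, in which the calls were shifted along the order of genes by every offset among the genes that could have been called. These p-values were adjusted by the Benjamini-Hochberg method over the 138 list tests of a mark, with 0.05 as the threshold. Adjusted over the list alone (6 tests of one list in one mark), 16 of the 138 H3K9me3 tests passed, against 6 over all lists. For H3K27me3 these numbers were 14 and 9. Gene calls rest on a rule of size and have no p-value of their own. The overlap of H3K9me3 loss with H3K27me3 gain and the relation to SETDB1 were tested two-sided against 10000 random rotations along the genome, which can give no p below 0.0002. SETDB1 peaks were kept where the libraries overlapped by at least 1 bp.

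The lists covered H3K9 methylation and HP1 machinery, Polycomb machinery, nucleic acid sensing, interferon stimulated genes, the type I interferon cluster, antigen presentation, domesticated retroviral genes, myeloid differentiation, leukaemia self-renewal, HOX clusters, developmental transcription factors, zinc finger genes of chromosome 19 and of other chromosomes, clustered protocadherins, olfactory receptors, cancer testis antigens, histone genes, keratins and keratin associated proteins, neuronal adhesion and channel genes, T cell genes, B cell genes, erythroid and megakaryocyte genes, and housekeeping genes. Named genes were the 5 lost and 5 gained genes with the largest difference per mark and knockout, up to 3 called members of each list ranked in the same way, and SUV39H1, SUV39H2 and SETDB1. Named regions were the 5 longest runs of lost and of gained bins per mark and comparison. Some genes and regions that these rules select are not reported here.

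The scripts were tested on simulated data. In H3K9me3 gene calls with 2 simulated knockout libraries, a lowering of 60 percentage points was recovered in 99.5% of 200 genes, one of 40 points in 84.0% and one of 15 points in 1.00%, with 73 to 87 false calls among 19774 unchanged genes. Simulated deviations were those of the 2 control libraries from their mean, which are narrower than the deviations of single libraries. Recovery may thus be overstated and false calls understated. The rotation test gave p under 0.05 for 4.70% of 2000 unrelated lists when neighbouring genes formed runs of random length. It did so for 9.40% when lists and calls shared one fixed grid of runs, so its p-values can be too small where a gene family and a domain have matching edges. The limma 3.58.1 fit used as an alternative, in R 4.3.3, recovered 52.5% of genes lowered by 40 points among 6226 genes, with 20 false calls.

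Reads inside domains ranged from 16.5 to 23.6 M (mega) per H3K9me3 library and from 47.9 to 70.7 M per H3K27me3 library. These are not library totals, which are not given in the lists. The alternatives were other bin sizes and marking thresholds, the upper 50% of each list by score, lists brought to equal covered length by score, a minimum width of 2 kb, autosomes alone, each library left out in turn, other gene thresholds, limma, a replicate block, Fisher's exact test and other SETDB1 overlaps. The 3 alternatives added after the data were seen left out chromosome 7, matched SETDB1-bound with unbound bins on control read density, and tested any knockout against sgControl. Transposable elements were not analysed here, since no repeat annotation was used.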

Results

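H3K9me3, a histone mark of heterochromatin, and H3K27me3, the mark set by Polycomb complexes, were mapped in U937 cells of 3 genotypes with 2 libraries each. SUV39H1 and SUV39H2 are H3K9 methyltransferases. SKO cells lack SUV39H1 and DKO cells lack both. SETDB1, a further H3K9 methyltransferase, was mapped in 2 libraries of wild-type cells. Reads inside H3K9me3 domains averaged 20.8 ± 3.97 M (mega) in sgControl, 20.6 ± 0.578 M in SKO and 18.6 ± 2.89 M in DKO (SD, n = 2). For H3K27me3 they averaged 49.4 ± 1.25, 65.3 ± 7.67 and 58.6 ± 15.1 M. The overlap of domains between libraries, as the Jaccard index, was 0.699 to 0.725 within a genotype for H3K9me3 and 0.478 to 0.506 between sgControl and either knockout. For H3K27me3 it was 0.907 to 0.921 within a genotype and 0.697 to 0.712 between sgControl and either knockout.

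The targeted genes carried neither mark. SUV39H1 and SUV39H2 had 0% of the gene body inside H3K9me3 or H3K27me3 domains in every library, so the domain lists neither check nor contradict the genotype labels. The SETDB1 gene had no H3K9me3 in sgControl, 20.8% of its body in both SKO libraries and 14.6% ± 2.94 in DKO (SD, n = 2), below the difference needed for a call. All 20 housekeeping genes were free of both marks in all libraries.

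The first comparison asked where H3K9me3 was present with and without SUV39H1. Desmosomal cadherin genes on chromosome 18, DSC2 and DSG3, lost the mark in SKO, as did KLF5, which encodes an epithelial transcription factor, MEP1B, which encodes a metalloprotease subunit, and BSPH1. Each was covered over 100% of its body in both sgControl libraries and 0% in both SKO libraries. In DKO, MEP1B and BSPH1 were covered over 74.3% ± 14.0 and 57.7% ± 13.8 (SD, n = 2). Marked regions lost by SKO summed to 277.59 Mb, which is 31.3% of the 886.86 Mb marked in both control libraries, and 90.1 Mb were gained. The other pairings of the same 4 libraries gave at most 14.0 Mb. By gene, 899 lost and 821 gained H3K9me3, against at most 60 in the other pairings. The domains covered 1028 ± 22.1 Mb in sgControl and 755 ± 1.55 Mb in SKO (SD, n = 2), a difference of -26.6%.

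The longest stretches lost in SKO held few genes. They lay on chromosome 2 from 193840001 to 194420000, on chromosome 13 from 64570001 to 65050000 and on chromosome 6 from 128010001 to 128430000, the last of them touching PTPRK, a receptor phosphatase gene. The longest gain was a gene-rich stretch on chromosome 6 from 35170001 to 35740000 with 10 genes, among them PPARD, a nuclear receptor gene, SCUBE3, ZNF76, FKBP5 and TEAD3. PPARD, SCUBE3 and ZNF76 rose from 0% to 100% of the gene body in both libraries of SKO and of DKO. BRPF3 on the same arm and RSPO4 on chromosome 20 rose from 0% to 100% in SKO, and to 94.5% ± 7.85 and 97.3% ± 3.79 in DKO (SD, n = 2). The loss was uneven over the chromosomes. Marked length in SKO was 0.418 times that of sgControl on chromosome 18 and 0.521 times on chromosome 4, while chromosome 19 had 20.3 Mb in sgControl and 22.3 Mb in SKO and chromosome 15 had 38.0 and 41.7 Mb.

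Among the gene lists, developmental transcription factors and neuronal adhesion and channel genes lost H3K9me3 in SKO more often than other genes. Of the developmental regulators that could be called, 16 of 28 lost the mark (adjusted p = 0.0302, exact rotation test), among them NKX6-1, DLX6 and SIX2, each from 100% to 0% in both libraries. Over the 80 genes of that list the mean covered share was 37.4% ± 3.21 in sgControl and 17.3% ± 2.11 in SKO (SD, n = 2). Of the neuronal genes, 18 of 30 lost the mark (adjusted p = 0.0252), including the adhesion and guidance genes CNTN6 (80.7% ± 4.91 to 0%) and ROBO1 (85.0% ± 0.29 to 5.88% ± 0.87). Zinc finger genes did so less often than other genes: 5 of 218 on chromosome 19 (adjusted p = 0.0302) and 11 of 135 elsewhere (adjusted p = 0.0377). The chromosome 19 zinc finger genes stayed covered over 85.9% ± 0.533 in sgControl and 87.8% ± 0.00452 in SKO.

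Other lists missed the threshold in SKO. Cancer testis antigens had 9 of 10 eligible genes called lost (adjusted p = 0.0556), with MAGEB2 and MAGEB4 on chromosome X at 100% in sgControl and 0% in SKO. Clustered protocadherins had 26 of 46 (adjusted p = 0.419), with PCDHB9 and PCDHB16 at 100% and 0%. Olfactory receptors had 54 of 196 and keratins 17 of 50 called lost (adjusted p = 1 for both). Zinc finger genes of other chromosomes had 17 of 141 and olfactory receptors 20 of 145 called gained (adjusted p = 0.0556 and 0.0962). Interferon stimulated genes had 2 of 10 called lost and 4 of 38 called gained (adjusted p = 1 for both). They included CXCL9, a chemokine gene covered over 0% in sgControl and 100% in SKO, and GBP4 (67.0% ± 8.51 in sgControl, 0% in SKO). In the nucleic acid sensing list 2 of 21 were called gained, among them the DNA sensor gene IFI16 (0% to 39.1% ± 10.3). Polycomb genes called gained were 2 of 23 (adjusted p = 1 for both lists), EZH2 (0% to 51.5% ± 8.09) and KDM6A (3.84% ± 5.43 to 45.6% ± 0.708), a writer and an eraser of H3K27me3. Domesticated retroviral genes had 1 of 6 called lost and 2 of 15 called gained (adjusted p = 1 for both). ERVFRD-1, which encodes a placental fusion protein, and RTL3 were at 0% in sgControl and 100% in SKO, and ERVMER34-1 was at 100% and 0%. The remaining lists had at most 1 gene called lost and 3 called gained except zinc finger genes of chromosome 19, with 6 of 32 gained (adjusted p = 0.354), and none passed.

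Several of these calls depended on how much of each list was used. With all H3K9me3 lists brought to the same covered length, SKO lost 157.71 Mb and gained 165.88 Mb, with 456 genes lost and 1329 gained, so the excess of loss over gain was not kept; that setting makes lost and gained lengths nearly equal by construction. By gene, gains also outnumbered losses with limma (1042 lost and 1446 gained), at a gene difference of 10 percentage points (1397 and 1710), with the upper 50% of domains by score (802 and 826) and without H3K9me3 SKO replicate 1 (1090 and 1132), so the balance of genes was not settled. At equal covered length the developmental list (7 genes, adjusted p = 0.539) and both zinc finger lists (adjusted p = 0.0639 and 0.213) missed the threshold, and the developmental list also did so without H3K9me3 SKO replicate 1 (0.0755) or 2 (0.0661), without chromosome 7 (0.0640), at a gene difference of 50 percentage points (0.0504) and with the upper 50% of domains by score (7 genes, adjusted p = 1). The zinc finger list of other chromosomes missed it on autosomes alone (0.0596). At 50 percentage points both zinc finger lists (0.0672 and 0.0845) and the neuronal list (0.0806) missed it, and the neuronal list did so without H3K9me3 SKO replicate 2 (0.0604).

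The next comparison asked where H3K9me3 was present without both SUV39H genes. DSG3 lost the mark from 100% to 0%, as did PDPN, the gene of the glycoprotein podoplanin, and on chromosome 7 ETV1, AGR3 and CYP3A4, the last of them encoding a drug-metabolising cytochrome. In SKO the last 4 had kept 11.0% ± 15.6, 5.30% ± 7.50, 45.4% ± 2.07 and 24.4% ± 31.2 (SD, n = 2). CYBB, which encodes the catalytic subunit of the phagocyte NADPH oxidase, and the leukotriene receptor gene CYSLTR1, both on chromosome X, gained it from 0% to 100%, and in SKO had 100% and 86.0% ± 4.70. DKO lost 250.06 Mb (28.2% of the control-marked length) and gained 90.3 Mb, against at most 16.8 Mb in the other pairings. By gene, 845 lost and 767 gained the mark, against at most 49. Covered length was 791 ± 5.01 Mb in DKO (SD, n = 2), a difference of -23.1% from sgControl. Over the 3 genotypes the trend was -119 Mb per gene targeted (p = 0.133, exact permutation test), while every knockout library lay below both control libraries (p = 0.0667, the smallest value an exact test of any knockout against sgControl can give, a test added after the data were seen). With all lists at equal length, DKO lost 148.09 Mb and gained 154.4 Mb, with 500 genes lost and 1163 gained. Genes gained also outnumbered genes lost with limma (1020 lost and 1200 gained), at a gene difference of 10 percentage points (1404 and 1511), with the upper 50% of domains by score (741 and 745), without chromosome 7 (686 and 756) and without H3K9me3 DKO replicate 1 (1106 and 1139). Without that library the length gained was 137 Mb.

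**Figure D1:**
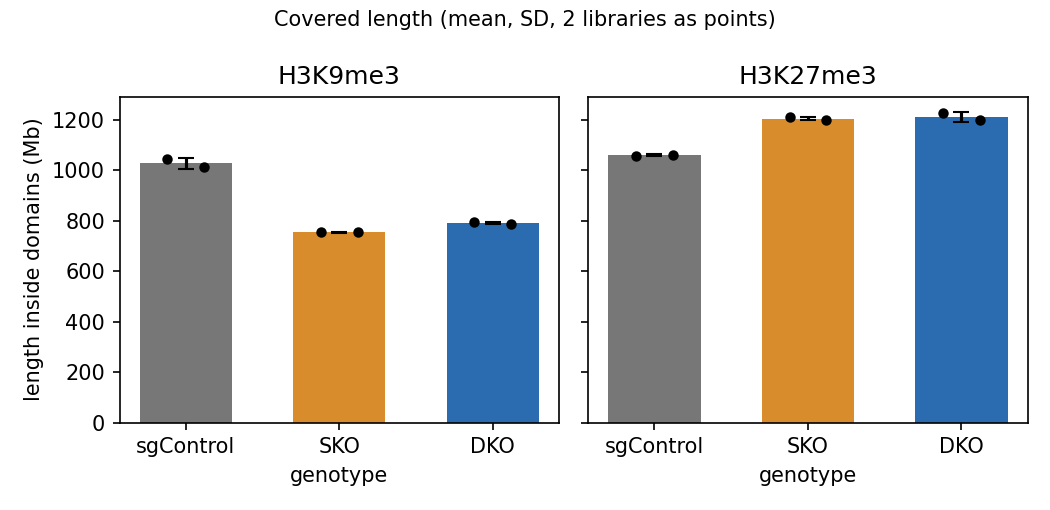
Length inside called domains (Mb, y axis) by genotype (x axis) for both marks, with bars as means, error bars as SD and points as the 2 libraries. H3K9me3 averaged 1028, 755 and 791 Mb and H3K27me3 1060.0, 1205 and 1212 Mb in sgControl, SKO and DKO.

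Chromosome 7 stood apart in DKO. It held 77.7 Mb of marked H3K9me3 bins in sgControl, 59.6 Mb in SKO and 25.5 Mb in DKO, and 63.9% of its control-marked length was lost in DKO. H3K27me3 on this chromosome spanned 62.4, 75.5 and 62.8 Mb. Without chromosome 7, DKO lost 206.82 Mb and 686 genes of H3K9me3. The longest DKO losses lay on chromosome 21 from 19790001 to 20300000 and on chromosome 7 from 19200001 to 19590000 and from 79660001 to 80050000. The longest gain was the same chromosome 6 stretch as in SKO, followed by one on chromosome X from 65920001 to 66140000 that touched VSIG4, a macrophage receptor gene.

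Read density inside domains also differed on chromosome 7. In bins marked in all 4 libraries, DKO over SKO and relative to the other chromosomes, it was 0.803 for H3K9me3 and 0.733 for H3K27me3. DKO over sgControl gave 0.938 and 0.827, and SKO over sgControl 1.04 and 1.08. Replicates of 1 genotype differed by at most 0.05 on the log2 scale on any chromosome.

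**Figure D2:**
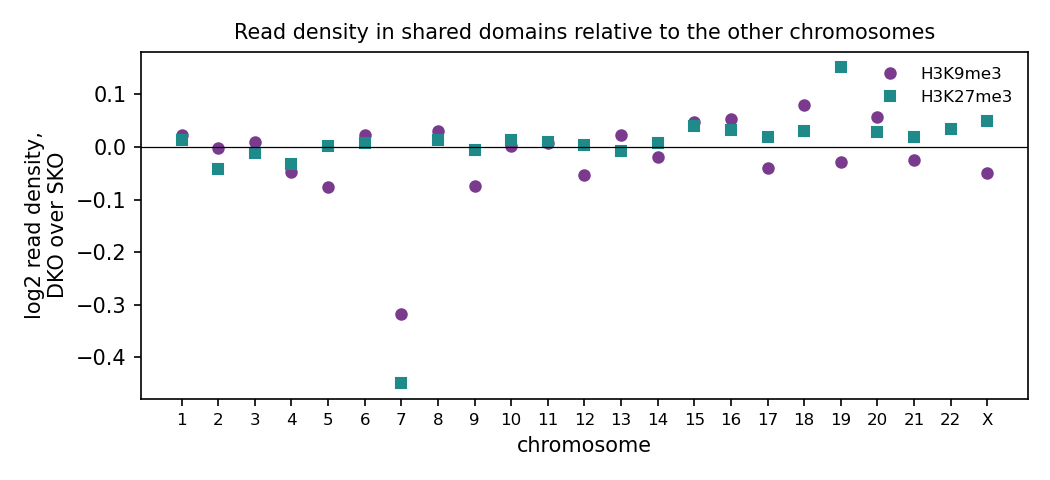
Log2 read density in bins marked in all 4 libraries, DKO over SKO and relative to the other chromosomes (y axis), for each chromosome (x axis), with circles for H3K9me3 and squares for H3K27me3. Chromosome 7 lies at -0.32 and -0.45.

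No gene list passed the threshold for H3K9me3 in DKO against sgControl. Developmental transcription factors had 14 of 28 called lost (adjusted p = 0.0556), with NKX6-1, DLX6 and ZIC2 at 100% in sgControl and 0% in DKO. Neuronal genes had 14 of 30 (adjusted p = 0.0856), including CSMD3 (65.4% ± 4.25 to 0.956% ± 0.792). Zinc finger genes had 7 of 218 called lost on chromosome 19 (adjusted p = 0.0809) and 13 of 135 elsewhere (adjusted p = 0.0566), and 17 of 141 of the latter were called gained (adjusted p = 0.0556). Olfactory receptors had 22 of 196 called lost (adjusted p = 0.397) and 20 of 145 called gained (adjusted p = 0.0752), protocadherins 22 of 46 called lost (adjusted p = 0.975) and cancer testis antigens 6 of 10 (adjusted p = 0.988). Interferon stimulated genes had 3 of 10 called lost and 3 of 38 called gained, and nucleic acid sensing genes 2 of 21 called gained, IFI16 and ZBP1 (0% to 58.8% ± 41.0), with adjusted p = 1 for each. Single calls in other lists included CD33, a myeloid surface receptor gene (0% to 63.6% ± 7.86). MECOM, a leukaemia-associated regulator, was covered over 59.0% ± 5.29 in sgControl and 17.1% ± 8.74 in DKO. The globin genes HBD and HBG1 and IFNB1 and IFNA6 of the type I interferon cluster rose from 0% to 100%. These 4 genes span 1646, 1589, 839 and 570 bp, so their values rest on few steps of the 800 bp domain grid. In SKO, IFNB1 and IFNA6 each averaged 50% ± 70.7 (SD, n = 2). Antigen presentation, HOX, T cell and B cell genes had at most 1 call in each direction. Histone genes had 2 of 2 called lost (adjusted p = 0.652), keratin genes 6 of 50 called lost and 6 of 93 called gained, domesticated retroviral genes 2 of 6 and 2 of 15 (adjusted p = 1 for each), and zinc finger genes of chromosome 19 had 6 of 32 called gained (adjusted p = 0.297). SETDB2, which encodes a relative of SETDB1, was the 1 call of 22 in the H3K9 methylation list (17.3% ± 2.23 to 59.9% ± 2.23).

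The bins lost or gained overlapped between the knockouts. Of the H3K9me3 length lost, 186.11 Mb was lost in both, where independent sets would share 78.3 Mb and simulated unchanged libraries set against the same controls shared 1.64 Mb. Of the length gained, 55.2 Mb was shared, against 4.51 and 1.46 Mb. For H3K27me3, 53.4 Mb was lost in both (5.37 and 0.545 Mb) and 199.63 Mb gained in both (27.4 and 0.324 Mb). Both comparisons used the same 2 control libraries, too few to split, so part of the excess may come from them.

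**Figure D3:**
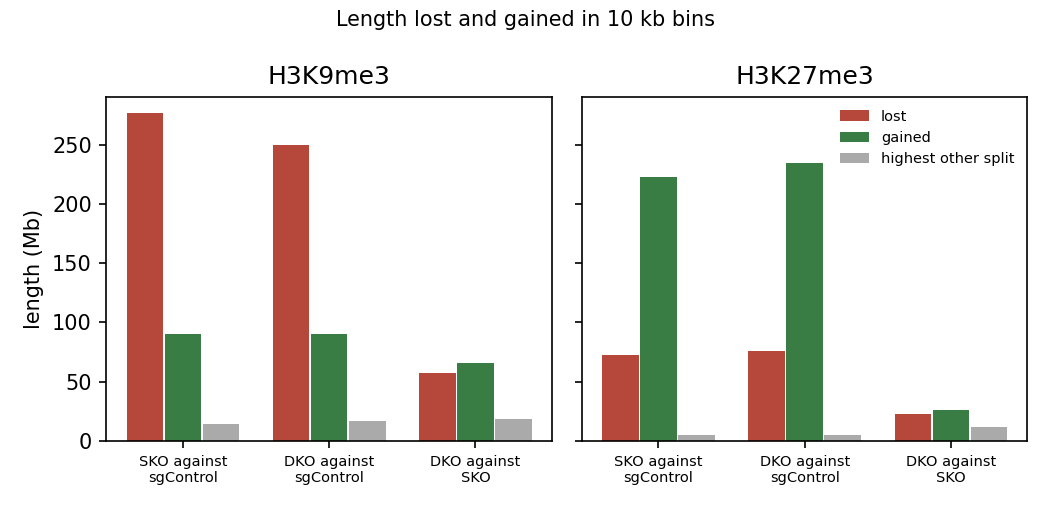
Length lost, length gained and the highest length in the other pairings of the same 4 libraries (Mb, y axis; bars from 10 kb bins) for the 3 comparisons (x axis) of each mark. H3K9me3 losses against sgControl were 277.59 and 250.06 Mb and H3K27me3 gains 223.06 and 235.17 Mb.

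H3K27me3 showed the reverse balance by length. ADGRL2, which encodes an adhesion receptor, and the cadherin gene DCHS2 gained it from 0% to 100% of the gene body in both libraries of SKO and of DKO, as did HOXD3, HOXD10 and HOXD11 and the homeobox gene OTX2. ADGRG6 also gained it from 0% to 100% in both. ABCB5 and CDH6 rose from 0% to 100% in SKO and to 96.8% ± 0.504 and 98.5% ± 2.09 in DKO (SD, n = 2). SHROOM3, SEMA3C and ADAM23 rose from 0% to 100% in DKO and to 99.4% ± 0.813, 98.9% ± 1.57 and 97.7% ± 3.19 in SKO. ADAMTS9, a metalloprotease gene, and IGFL4 lost it from 100% to 0% in both knockouts, as did LBH and NPHS1, the gene of the podocyte protein nephrin. NOVA2, a neuronal splicing factor gene, KIF26A and BTBD16 lost it from 100% to 0% in SKO and kept 28.6% ± 1.41, 7.56% ± 10.7 and 22.1% ± 16.1 in DKO. In SKO 223.06 Mb was gained and 72.4 Mb lost, against at most 4.28 Mb in the other pairings. In DKO 235.17 Mb was gained and 76.3 Mb lost, against at most 4.97 Mb.

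By gene, 674 gained and 630 lost H3K27me3 in SKO, and 763 gained and 600 lost it in DKO, against at most 10 and 11 in the other pairings. Covered length averaged 1060.0 ± 3.50 Mb in sgControl, 1205 ± 7.21 Mb in SKO and 1212 ± 19.3 Mb in DKO (SD, n = 2). The trend of 75.9 Mb per gene targeted missed the threshold (p = 0.0667, exact permutation test), and passed it without chromosome 7 (76.0 Mb, p = 0.0222) or without H3K27me3 DKO replicate 2 (91.6 Mb, p = 0.0333). Domains were more numerous and shorter in the knockouts, with 10413, 15860 and 15451 domains on average (trend p = 0.111, exact). The width above which domains held 50% of the covered length was 282 ± 17.0 kb in sgControl, 192 ± 5.09 kb in SKO and 185 ± 13.6 kb in DKO (SD, n = 2; trend p = 0.0444, exact permutation test, not adjusted for the other measures tested). With all lists at equal covered length, SKO gained 167.62 and lost 144.13 Mb and DKO gained 176.68 and lost 151.46 Mb, but genes lost (893 and 866) then outnumbered genes gained (518 and 582). They did so with limma too, by 924 to 822 in SKO and 916 to 894 in DKO. In SKO this also held at a gene difference of 10 percentage points (949 to 855), on autosomes alone (617 to 586), without H3K27me3 sgControl replicate 1 (753 to 728) or 2 (763 to 725) and without H3K27me3 SKO replicate 1 (734 to 718).

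Long H3K27me3 gains ran on chromosome 21 from 23700001 to 24990000 and on chromosome 2 from 145420001 to 146950000 in DKO (from 145710001 in SKO), both without a protein-coding gene. On chromosome 1, from 67740001 to 68730000, SKO gained a stretch with GNG12, DIRAS3, WLS, RPE65 and DEPDC1. The longest losses were on chromosome 9 from 78430001 to 78970000 in SKO and on chromosome 3 from 64510001 to 64860000, over ADAMTS9, in both knockouts. Chromosome X carried 36.6 Mb of marked bins in sgControl, 69.6 Mb in SKO and 77.8 Mb in DKO, ratios of 1.90 and 2.13.

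Olfactory receptors gained H3K27me3 more often and lost it less often than other genes in both knockouts. In SKO 23 of 134 gained it (adjusted p = 0.00804, exact rotation test) and in DKO 28 of 134 (adjusted p = 0.0107), including OR4K17 from 0% to 100% in both. Only 15 of 261 and 14 of 261 lost it (adjusted p = 0.0122 for each), and 22 did so in DKO without H3K27me3 DKO replicate 1. The list mean was 65.9% ± 0.104 in sgControl, 67.4% ± 0.161 in SKO and 69.1% ± 0.916 in DKO (SD, n = 2). None of 44 neuronal adhesion and channel genes lost the mark in SKO (adjusted p = 0.0190) or DKO (adjusted p = 0.0122), and 5 of 13 and 4 of 13 were called gained (adjusted p = 0.0526 and 0.210), CNTNAP4, ERBB4 and CDH9 among them. CNTNAP4 was covered over 20.2% ± 2.25 in sgControl and 95.2% ± 0.799 in SKO. Zinc finger genes of chromosome 19 gained the mark in DKO, where 45 of 188 were called (adjusted p = 0.0161), including ZNF626, ZNF737 and ZNF99 from 0% to 100%. In SKO 12 of 188 were called gained and 32 of 64 lost (adjusted p = 1 and 0.143).

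Other lists did not pass for H3K27me3. HOX genes had 7 of 37 called gained in each knockout (adjusted p = 0.438 and 0.480), and the mean over the 39 HOX genes was 3.85% ± 1.81 in sgControl, 19.7% ± 0.275 in SKO and 20.5% ± 0 in DKO (SD, n = 2). Developmental transcription factors had 12 and 9 of 35 called lost (adjusted p = 0.480 and 1) and 6 and 7 of 48 called gained (adjusted p = 0.284 and 0.177). Keratin genes had 24 and 29 of 80 called lost (adjusted p = 1 and 0.480), KRT9 at 100% in sgControl and 0% in both knockouts, and the list mean was 54.3% ± 0.0707, 37.4% ± 1.77 and 35.6% ± 0.0435. Zinc finger genes of other chromosomes had 20 and 12 of 46 called lost (adjusted p = 0.0513 and 1). Antigen presentation genes averaged 17.9% ± 1.32, 8.18% ± 2.68 and 9.19% ± 1.68, with 2 of 5 called lost in each (adjusted p = 1), HLA-DPA1 among them. Interferon stimulated genes had 3 of 5 called lost in each (adjusted p = 0.556 and 0.496), with MX1 at 58.0% ± 32.2 in sgControl and 0% in both knockouts, and 2 of 41 called gained, IFI44L and IFI44 (100% in both knockouts). T cell genes had 2 of 2 called lost, GATA3 and BCL11B (adjusted p = 0.480 in each), and RAG1, ALAS2 and ARC were also called lost in both. Cancer testis antigens had 4 and 5 of 59 called gained, MAGEC1 and MAGEC2 among them (adjusted p = 1). H3K9 and Polycomb machinery, histone, type I interferon, myeloid and leukaemia self-renewal genes had no H3K27me3 call in either knockout, nor did nucleic acid sensing genes. Protocadherins had 1 of 25 called lost in SKO and 0 in DKO, and zinc finger genes of other chromosomes 8 and 11 of 231 called gained (adjusted p = 1 for each).

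At equal covered length the olfactory gain in SKO (16 genes, adjusted p = 0.0574) and the absence of neuronal losses (4 genes in each knockout, adjusted p = 0.0774) no longer passed. At a gene difference of 50 percentage points the low rate of olfactory losses (14 and 12 genes, adjusted p = 0.322 and 0.159) and of neuronal losses (0 genes, adjusted p = 0.159 and 0.191) did not pass either.

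DKO against SKO asked what the additional loss of SUV39H2 went with. Zinc finger genes, many of which encode transcriptional repressors, gained H3K27me3. On chromosome 19, 52 of 204 did so in DKO (adjusted p = 0.0122, exact rotation test), and 13 of 239 zinc finger genes elsewhere (adjusted p = 0.00804). Over the 246 genes on chromosome 19 the covered share was 25.3% ± 0.0359 in sgControl, 19.2% ± 0.246 in SKO and 37.4% ± 0.75 in DKO (SD, n = 2). One of the longest gained runs, on chromosome 19 from 52770001 to 52860000, touched ZNF600, ZNF28, ZNF468 and ZNF320, and another, from 37570001 to 37640000, touched ZNF540, ZNF571 and ZFP30. ZNF468, which the rule for named genes did not select, had 0% in all sgControl and SKO libraries and 100% in both DKO libraries.

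**Figure D4:**
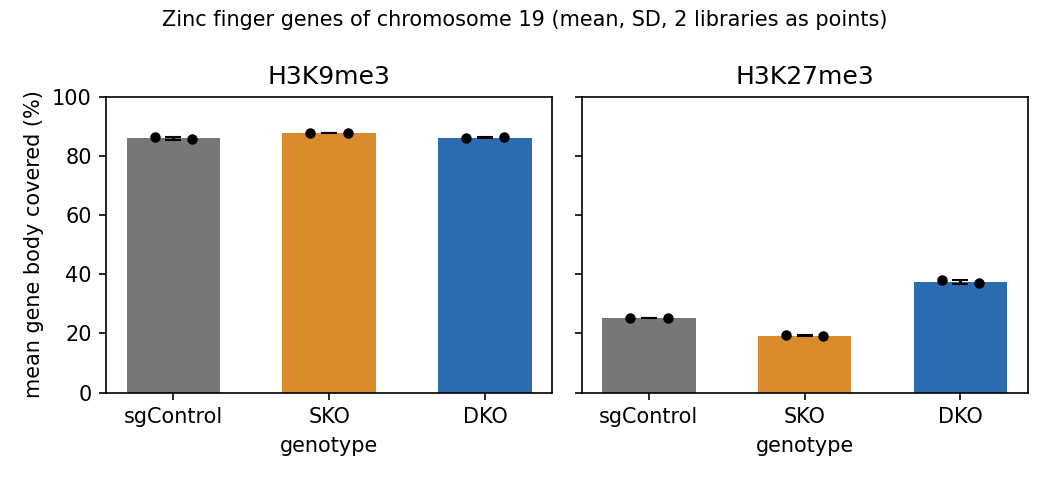
Mean percentage of the gene body inside domains (y axis) over 246 zinc finger genes of chromosome 19 by genotype (x axis) and mark, with bars as means, error bars as SD and points as the 2 libraries. H3K27me3 averaged 25.3, 19.2 and 37.4% and H3K9me3 85.9, 87.8 and 86.1% in sgControl, SKO and DKO.

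**Figure D5:**
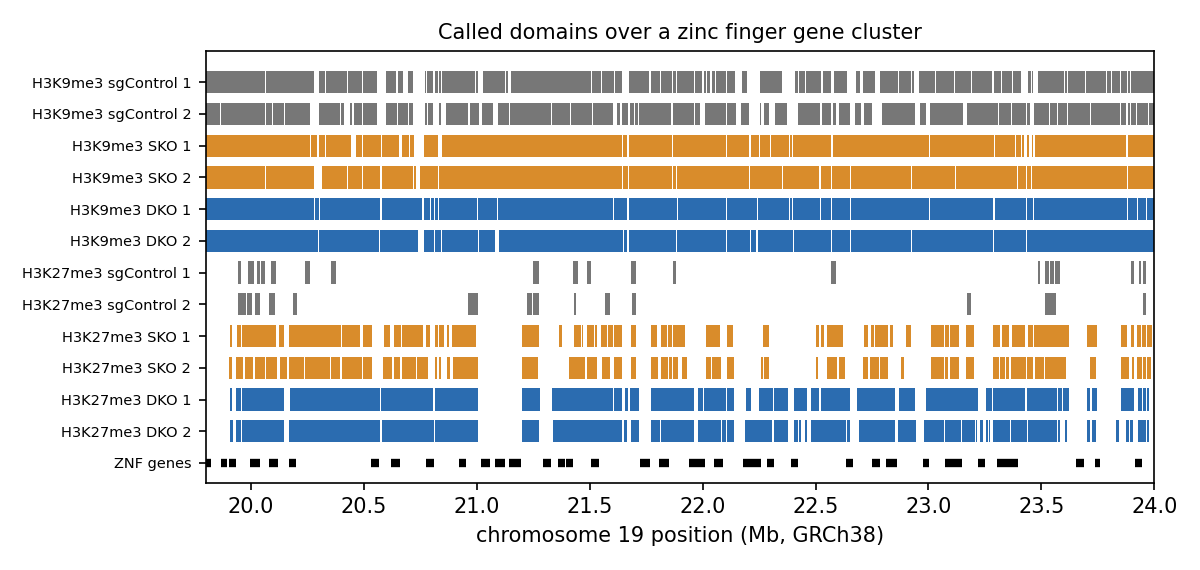
Called domains of the 12 libraries, 1 track each, on chromosome 19 from 19.8 to 24 Mb (x axis, GRCh38), with the 34 zinc finger genes of the region as black boxes. H3K9me3 domains span most of the region in every genotype, and H3K27me3 domains cover more of it in SKO than in sgControl and most in DKO, whereas over all 246 zinc finger genes of the chromosome SKO (19.2%) lay below sgControl (25.3%).

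For H3K9me3, olfactory receptors and neuronal genes gained the mark in DKO against SKO, 33 of 205 and 7 of 47 (adjusted p = 0.0157 for each, exact rotation test). Olfactory receptors called gained numbered 56 and 50 without H3K9me3 SKO replicate 1 and 2, 52 and 61 without H3K9me3 DKO replicate 1 and 2, and 20 with the upper 50% of domains by score, and passed each time. The olfactory list averaged 56.3% ± 1.77 in sgControl, 42.3% ± 0.480 in SKO and 54.0% ± 1.85 in DKO (SD, n = 2), and the neuronal list 49.0% ± 0.580, 23.6% ± 0.0425 and 32.4% ± 1.61. The 7 neuronal genes, named after their values were seen, were CSMD1, DCC, GRM7, MACROD2 and SLIT3, all of which had lost the mark in SKO, and NTM and OPCML, neighbours on chromosome 11 that also gained it against sgControl. The longest gained run lay in CNTN4 on chromosome 3 from 2470001 to 2570000. Keratin genes had 12 of 107 called gained (adjusted p = 0.0556). In all, DKO lost 57.5 Mb and 267 genes of H3K9me3 against SKO and gained 66.1 Mb and 291 genes, against at most 18.3 Mb and 54 genes in the other pairings. The excess of gain was not kept at equal covered length (66.4 Mb and 324 genes lost, 54.0 Mb and 236 genes gained). By gene it also turned with limma (270 lost and 208 gained), at a gene difference of 10 percentage points (727 and 631) and without H3K9me3 SKO replicate 1 (505 and 483). For H3K27me3 DKO lost 22.5 Mb and 73 genes and gained 25.5 Mb and 145 genes, against 11.4 Mb and 20 genes. By length, losses exceeded gains at equal covered length (29.4 and 26.8 Mb), with the upper 50% of domains by score (29.8 and 27.1 Mb), on autosomes alone (21.96 and 21.62 Mb) and without H3K27me3 DKO replicate 1 (53.2 and 41.4 Mb). Olfactory receptors had 0 of 266 called lost for H3K27me3 (adjusted p = 0.210), and the remaining lists of this comparison passed for neither mark.

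Chromosome 7 carried a good part of the DKO losses against SKO. Without it, H3K9me3 losses were 36.8 Mb and 136 genes and H3K27me3 losses 14.7 Mb and 45 genes, and of the 5 longest H3K27me3 losses 4 lay on that chromosome, the longest from 46370001 to 46810000. Leaving out a library, which leaves fewer that have to concur, raised the H3K9me3 losses to 104 and 103 Mb without H3K9me3 SKO replicate 1 and 2 and to 95.7 and 96.3 Mb without H3K9me3 DKO replicate 1 and 2, and the gains to 112, 110.5, 131 and 139 Mb in the same order. Without the H3K27me3 libraries of the same names the H3K27me3 losses became 36.6, 38.2, 53.2 and 40.2 Mb and the gains 53.1, 47.1, 41.4 and 47.2 Mb. The gain of zinc finger genes of other chromosomes missed the threshold at equal covered length (10 genes, adjusted p = 0.0631) and at a gene difference of 50 percentage points (5 genes, 0.306), where the neuronal gain held no gene.

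Whether H3K27me3 was gained where H3K9me3 was lost was asked in bins that carried H3K9me3 alone in sgControl. In SKO 43.3 Mb of these bins lost H3K9me3 and gained H3K27me3, 1.55 times the 27.9 Mb found on average over rotations (p = 0.0002, rotation permutation test, the smallest the rotations can give). H3K27me3 was gained by 49.3% of the length that lost H3K9me3 and by 25.9% of the remainder. In DKO the overlap of 37.2 Mb was 1.04 times the rotation mean of 35.9 Mb (p = 0.450, rotation permutation test), with 33.8% and 32.1%. Without H3K9me3 DKO replicate 1 this became 1.09 times (p = 0.0188, rotation permutation test). The difference between SKO and DKO was not tested. Bins with both marks in sgControl more often kept H3K27me3 alone: 174.85 Mb did so in SKO and 119.92 Mb in DKO, while 13.1 and 11.7 Mb kept H3K9me3 alone.

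SETDB1 was bound at zinc finger genes. The libraries listed 23430 and 24367 peaks, and 12304 peaks of replicate 1 (52.5%) were also called in replicate 2. Chromosome 19 held 11.9% of these shared peaks and 1.93% of the genome length. A peak lay in or within 2 kb of 213 of 246 zinc finger genes of chromosome 19 (86.6%) and 149 of 263 elsewhere (56.7%), against 18.1% of all genes (adjusted p = 0.000576 for each, rotation test). The highest-ranked peaks of list genes were at ZNF12 on chromosome 7, ZNF557, ZNF180 and ZNF555 on chromosome 19 and ZNF596 on chromosome 8. All 5 kept H3K9me3 over at least 98.1% of the gene body in every genotype. Neuronal genes also had peaks more often (19 of 50, adjusted p = 0.00576), while olfactory receptors (12 of 392), developmental transcription factors (2 of 80), cancer testis antigens (0 of 82) and keratin genes (10 of 149) had them less often (adjusted p = 0.000576, 0.000576, 0.00322 and 0.0438). Protocadherins had peaks at 22 of 53, antigen presentation genes at 0 of 25 and interferon stimulated genes at 6 of 45 (adjusted p = 0.122, 0.112 and 0.686), and no remaining list passed.

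Most SETDB1 peaks lay in H3K9me3 domains, and those domains were rarely lost. The share inside H3K9me3 domains was 67.3% ± 1.80 in sgControl, 84.6% ± 0.0862 in SKO and 82.9% ± 0.994 in DKO (SD, n = 2), against 37.5%, 29.1% and 30.0% over rotations. Inside H3K27me3 domains it was 14.5% ± 0.0862, 11.0% ± 0.270 and 12.7% ± 0.529, against 35.0%, 38.7% and 39.1%. Of the control-marked length bound by SETDB1, 1.46% lost H3K9me3 in SKO and 3.0% in DKO, and of the unbound length 33.4% and 30.0% (p = 0.0002 for each, rotation permutation test, the smallest the 10000 rotations can give). The difference of -32.0 percentage points in SKO and -27.0 in DKO shrank to -15.9 and -12.3 when bound and unbound bins were matched on control read density, a test chosen after the data were seen (p = 0.001 for each, rotation permutation test, the smallest that 2000 rotations can give). SETDB1 was mapped in wild-type cells alone, so its position in the knockouts was not analysed here.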

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

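Of the tests given here, the count of chromosome 7 segments, the gap between zinc finger list means and the density of whole chromosomes beside H3K27me3 gains were chosen only after the result was seen, as was the use of the overlap of H3K9me3 loss with H3K27me3 gain in SKO to test an explanation, while that overlap itself was planned. In DKO against SKO, 33 olfactory receptors and 7 neuronal genes gained H3K9me3. For H3K27me3, the gains were 52 zinc finger genes of chromosome 19 and 13 of other chromosomes. Each list passed its own exact rotation test against the other genes, which does not measure the spread between libraries. H3K27me3 DKO replicate 2 had a domain of 7.2 kb on the mitochondrial chromosome, where every other H3K9me3 and H3K27me3 library, DKO replicate 1 included, had 0 kb.

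H3K27me3 over the zinc finger genes of chromosome 19 was higher in DKO than in SKO. Extra copies of the chromosome would raise its other genes too, and 1.35% of those gained the mark against 25.5% of the zinc finger genes. That count cannot exclude extra copies, since only 0.843% of all eligible genes in the genome gained the mark. Log2 read density on chromosome 19, DKO over SKO and relative to other chromosomes, was 0.151 for H3K27me3, the highest of any. For H3K9me3, which extra copies would raise too, it was -0.029. The other pairings of the 4 libraries called 0 of the 246 zinc finger genes, which decides nothing because they cannot part any of the 52. The mean over the 246 genes had a gap between SKO and DKO of 16.5 times the larger difference between replicates. That mean includes the 52 genes, which were called by the same gap, so it is no independent check against spread between replicates. Loss of called H3K9me3 domains from the same genes was absent, since 0% of the 52 had an H3K9me3 share at least 25 percentage points lower in DKO. Their share averaged 98.9% ± 0.375 in SKO and 98.4% ± 0.198 in DKO (SD, n = 2). Read density of H3K9me3 inside the domains of these 52 genes alone was not measured. Over all chromosome 19 bins marked in the 4 libraries, relative H3K9me3 density differed little between DKO and SKO (log2 -0.029). A lower total amount of the mark cannot be seen in these lists. Over the 52, chosen by this gap, H3K27me3 covered 40.3% ± 3.32 in sgControl, 9.07% ± 1.28 in SKO and 77.8% ± 0.0417 in DKO (SD, n = 2). Part of the gap was thus a fall in SKO below sgControl. An effect of SUV39H2 may remain as a hypothesis. The labels give no second SKO or DKO line, so a property of either line stays open and cannot be told apart from it.

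Chromosome 7 carried less of both marks in DKO than in SKO. A change on part of the chromosome is argued against, since 8 of its 8 segments of 20 Mb had an H3K9me3 length in DKO below 0.75 of that in SKO. Fewer copies in the DKO line may account for it, with a bound of -0.32 set beforehand on the log2 density of both marks. H3K27me3 passed that bound, and H3K9me3, at -0.316595, fell just short of it. Against sgControl the values were weaker, -0.09 for H3K9me3 and -0.27 for H3K27me3, where the former lay within the range of the other chromosomes (-0.29 to 0.59) and the latter below all of them (lowest -0.06), so copy number cannot be told apart from a loss of both marks without the input libraries.

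H3K27me3 was gained over long stretches in both knockouts. With lists at equal covered length, 176.68 Mb was still gained in DKO, against 2.77 Mb in the other pairings. That level is held low, because the other pairings cannot call bins that differ by genotype. Equal lengths also force gained and lost lengths close together. Some gained bins thus remained without a difference in list length, but how much of the gain list length accounts for was not settled. Entry of H3K27me3 where H3K9me3 was lost may account for part of it in SKO, where the overlap was 1.55 times its rotation mean, but in DKO it was 1.04 times. Extra copies of whole chromosomes are argued against, since 0% of the gained length lay on chromosomes whose log2 H3K27me3 density over sgControl, in bins marked in all 4 libraries and relative to the other chromosomes, was above 0.15. Extra copies of segments stay open, since of the gained length in 5 Mb windows with enough marked bins, 28.2% in SKO and 22.2% in DKO lay in windows above that density, between the bounds of 10 and 50% set beforehand. The H3K9me3 length lost over gained in the gained bins, 12.7 in SKO and 6.76 in DKO, lay above 3.08 and 2.77 over all bins, which extra copies would not bring, but all bins already passed the bound of 2 and the difference was not tested.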

How the results depend on the processing

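The tests without chromosome 7 were chosen only after the result was seen. Of 587 alternatives to 45 results, 493 kept direction and side of the threshold or, for lengths and counts without a p-value, stayed within 1.5 times. Of the remainder, 68 moved further, 22 no longer passed, 3 newly passed and 1 reversed. Each length or gene count was compared with its own value alone, so a turned balance of lost and gained is not counted as reversed. The cause was not tested except where stated. A window around promoters (promoter window) was not run, and the equal-length setting gives no trend of covered length, which it fixes. Without library totals or input, depth limits how short or weak a domain could be called, and this could not be measured.

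With the upper 50% of each list by score, developmental factors losing H3K9me3 in SKO numbered 7, olfactory receptors gaining it in DKO against SKO 20, and H3K27me3 lost and gained in DKO against SKO were 29.8 and 27.1 Mb. At equal covered length, H3K9me3 lost and gained were 157.71 and 165.88 Mb in SKO (456 and 1329 genes) and 148.09 and 154.4 Mb in DKO (500 and 1163 genes), and H3K27me3 lost was 144.13 and 151.46 Mb; in DKO against SKO, H3K9me3 lost and gained were 66.4 and 54.0 Mb (324 and 236 genes) and H3K27me3 29.4 and 26.8 Mb, the reverse of the reported balance. Equal lengths force losses and gains close together. The lists then held 7 developmental, 4 chromosome 19 zinc finger, 9 other zinc finger and 11 neuronal genes losing H3K9me3 in SKO, 4 neuronal genes losing H3K27me3 in each knockout, 23 and 26 olfactory receptors losing it in SKO and DKO, 16 olfactory receptors gaining it in SKO and 10 other zinc finger genes gaining it in DKO against SKO. On autosomes alone, 11 other zinc finger genes lost H3K9me3 in SKO, with adjusted p = 0.0596. Without chromosome 7, the H3K27me3 trend was 76.0 Mb, DKO losses against SKO were 36.8 Mb and 136 genes for H3K9me3 and 14.65 Mb and 45 genes for H3K27me3, and 14 developmental factors lost H3K9me3 in SKO.

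At a gene difference of 50 percentage points, H3K9me3 genes lost and gained were 456 and 302 in SKO, 415 and 304 in DKO and 74 and 104 in DKO against SKO; H3K27me3 genes lost were 348 and 328, and 29 lost and 72 gained in DKO against SKO. The lists held 13 developmental, 2 chromosome 19 zinc finger, 7 other zinc finger and 11 neuronal genes losing H3K9me3 in SKO, 0 neuronal genes gaining it in DKO against SKO (the reversed result), 14 and 12 olfactory receptors and 0 and 0 neuronal genes losing H3K27me3 in SKO and DKO, and 34 chromosome 19 and 5 other zinc finger genes gaining it in DKO against SKO. At 10 points the H3K9me3 counts were 1397 and 1710, 1404 and 1511, and 727 and 631, and H3K27me3 losses were 949 and 916, with 168 lost and 309 gained in DKO against SKO; 28 neuronal genes lost H3K9me3 in SKO, and 15 gained it and 21 other zinc finger genes gained H3K27me3 in DKO against SKO. With limma, genes lost and gained were 1042 and 1446 in SKO and 1020 and 1200 in DKO for H3K9me3, and 924 and 822 in SKO and 916 and 894 in DKO for H3K27me3, so the balance of genes turned for both marks; in DKO against SKO they were 270 and 208 for H3K9me3, again turned, and 108 and 191 for H3K27me3.

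With each library left out in turn, fewer libraries had to concur. H3K9me3 gained in DKO was 120.91 to 136.97 Mb. In DKO against SKO, H3K9me3 lost was 95.72 to 104.3 Mb and 446 to 505 genes, gained 110.45 to 138.85 Mb and 471 to 571 genes, and H3K27me3 lost 36.61 to 53.21 Mb and 114 to 144 genes, gained 41.35 to 53.06 Mb and 200 to 235 genes. Developmental factors losing H3K9me3 in SKO numbered 16 to 24, and neuronal genes 18 to 20. Olfactory receptors gaining H3K9me3 in DKO against SKO numbered 50 to 61, and those losing H3K27me3 in DKO 16 to 22. The replacement ratio in DKO was 1.00 to 1.09 and the H3K27me3 trend 64.9 to 91.6 Mb.

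Replicate numbers did not pair the libraries, with correlations of replicate differences between -0.00657 and 0.00990. With a replicate block, genes lost and gained were 953 and 872, 901 and 815, and 308 and 333 for H3K9me3 (SKO, DKO and DKO against SKO) and 651 and 677, 619 and 774, and 79 and 158 for H3K27me3. The paired trends of -119 and 75.9 Mb had exact p = 0.222 and 0.111, and no list or trend changed its side of the threshold.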

Other observations

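The comparison of reads inside domains was chosen only after the result was seen. Changes of H3K9me3 length also differed between chromosomes outside the comparisons above. Marked length on chromosome 21, gained bins included, was 0.543 times that of sgControl in SKO and 0.623 times in DKO, and on chromosome 3 it was 0.590 and 0.662 times. Chromosome 16 held 11.9 Mb in sgControl, 13.1 Mb in SKO and 16.4 Mb in DKO, and chromosome 20 held 27.7, 29.6 and 32.3 Mb.

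H3K9me3 lost in DKO was 148.09 Mb at equal covered length, against 10.9 Mb at most in the other pairings. That level is held low, because the other pairings cannot call bins that differ by genotype. The SKO library with the most reads inside H3K9me3 domains had 1.17 times the reads of the sgControl library with the fewest, while it covered a shorter length. These libraries were the extremes of their genotypes. Mean reads inside domains were 20.8 M in sgControl, 20.6 M in SKO and 18.6 M in DKO. Such reads depend on the calls and are not library totals, so the comparison cannot decide on an effect of depth.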
